A study of Mus musculus with 6 samples.

How the data were processed

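The deposited data are gene-level RNA-seq counts for 6 libraries of mouse intestinal adenoma tumoroids, 3 knock-out and 3 wild-type for Chuk. Per the labels' protocols, total RNA of 3 biological replicates per condition was extracted and stranded, polyA-selected libraries were prepared. Per the submitters' processing notes, reads were aligned with STAR to GRCm38. The version of STAR, the counting program, its strand setting, its handling of reads that map to several places and the annotation release are not given in the sources used here. The values the authors deposited are whole-number counts per Ensembl gene, not normalized, from 20749747 to 31875723 in all per library. Each table holds the same 49585 gene identifiers in the same order with no summary lines, and 26250 of them are at 0 in all libraries. Symbols, gene types and coordinates were taken from the GENCODE annotation of GRCm38, which named 49326 of the identifiers and left 259 unnamed. The polyA selection limits the data to polyadenylated RNA. A further limit is that 6 mitochondrial protein genes were at 0 in all libraries, so they add nothing to the mitochondrial share of counts.

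Libraries were grouped by the genotype and replicate number in the labels. Before averaging, each pair of libraries was compared by a chi-square statistic of counts per degree of freedom, which was 5.86 to 40.2 within genotypes, so no pair agreed within sampling noise and all 6 libraries were counted as separate. In knock-out replicate 2 it was 39.7 and 40.2 against the other knock-out libraries, which had 5.86 between themselves.

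The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with genotype as the only term, TMM scaling and the filterByExpr filter (minimum count 10, minimum total 15), which left 13759 genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values are counts relative to library size after TMM scaling, given as mean ± SD over 3 libraries. Fold changes are from the fitted model, and standard errors were computed from its negative binomial weights and quasi-likelihood dispersion. Where a genotype had no count, a bound was set at 3 counts over its pooled libraries. For genes selected by the rule below with 1 to 3 counts in a genotype, the ratio was given with an exact 95% interval for counts. At these depths a CPM of 1 corresponds to 20.7 to 31.9 counts per library.

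The genes named were set by a rule fixed before the data were examined. They are Chuk and 6 further IKK and NF-kB subunit genes, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher genotype and no overlap between the genotypes, the 5 smallest p-values, and up to 3 members per list with the smallest adjusted p. Some items that this rule selects are not reported here. Genes outside the rule are named as examples of a count or were chosen after their values were seen. The 38 gene lists, which include markers of other cell types, were fixed at the same time, and 36 had the minimum of 5 tested members. Lists were tested against all other genes with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the 36 lists, and again with a correlation estimated per list. The self-contained test fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, called 30 lists.

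Alternatives were fixed before the data were examined. They were scaling by DESeq2 1.42.0 size factors, by upper quartile or by library size alone, no filter or a filter of 1 CPM in 3 libraries, the Wald test of DESeq2, limma voom, the legacy edgeR fit, a term for the replicate number, an adjusted p of 0.01, protein-coding genes only, and leaving out each library in turn. One was chosen after seeing the data, leaving out chromosomes X, Y and 5 and the mitochondrial genome. Chromosome shifts were medians over genes with a mean of at least 5 CPM over all libraries, on log2 CPM with 0.5 added for the values per library.

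The tests were run first on simulated data made from the real means, library sizes and dispersions. For the comparison of knock-out with wild type, on 13759 genes with 200 changed, 14% of the 50 genes changed 1.25-fold, 50% of those changed 1.5-fold, 76% of those changed 2-fold and 90% of those changed 4-fold were recovered, and 10 of 125 calls (8%) were false at a nominal 5%. Only 200 genes were changed there, against 7896 genes called in the real data. The adjustment therefore set a stricter cut-off on the unadjusted p in the simulation, so these shares do not carry over to the real comparison. Simulated lists of 25 genes changed 1.5-fold were called in the right direction. One unchanged list tested beside them had an adjusted p of 0.04, and of 200 further unchanged lists 6 (3%) had an unadjusted p under 0.05 and 0 passed the adjustment. The simulated genes were drawn independently of each other, so these runs do not show how the preset correlation performs for correlated genes. In the real data the estimated correlation ran from -0.1085, for the distal small intestine and colon list, to 0.84, for the mitochondrially encoded list.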

Results

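RNA was sequenced from tumoroids, cultures grown in Matrigel from intestinal adenoma cells of C57BL/6 mice that carried the Min mutation in 1 copy of Apc and Cre driven by the Villin promoter, which is active in the intestinal epithelium. In the knock-out cultures, Cre acted on floxed alleles of Chuk, the gene that encodes the kinase IKKa, a subunit of the complex that switches on the transcription factor NF-kB. The comparison asks how the transcriptome of the tumour cells differed between cultures without and with an intact Chuk gene, with 3 knock-out and 3 wild-type libraries. Library depth was 29847360 ± 2697582 counts in the knock-out and 25759467 ± 4586682 in the wild type (mean ± SD, n = 3 each), over a range of 20749747 to 31875723. The labels call the 3 libraries of a genotype biological replicates without stating whether they came from separate mice or separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

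Chuk (ENSMUSG00000025199, GRCm38 chromosome 19, 44073335 to 44107480, minus strand) fell 3.42-fold in the knock-out, from 101 ± 5.21 to 29.4 ± 5.28 CPM (TMM-scaled counts relative to library size, mean ± SD, n = 3 each). Its log2 fold change was -1.77 with a standard error of 0.20 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.6e-08), and every knock-out library lay below every wild-type library. A total of 2648 Chuk counts remained in the knock-out libraries against 7775 in the wild type. A count per gene does not separate the floxed exons from the rest of the transcript, so the residual counts do not show whether an intact message was left. Of the partner subunits, Ikbkg, the regulatory subunit of the kinase complex, rose 1.94-fold to 125 ± 9.69 CPM (adjusted p = 3.7e-06). Ikbkg lies on chromosome X, and the genotypes also differed in sex-linked expression, as given below. Ikbkb, the other catalytic subunit, had 103 ± 4.66 CPM against 94.0 ± 2.64 (adjusted p = 0.19). Among the NF-kB subunits, Relb fell 2.05-fold (adjusted p = 2e-06) and Nfkb1 fell 1.79-fold (adjusted p = 6.4e-07). Rela, at 104 ± 4.74 CPM against 93.0 ± 4.54 (adjusted p = 0.096), and Nfkb2, at 66.8 ± 3.26 against 64.0 ± 9.83 (adjusted p = 0.64), did not pass the test.

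**Figure D1:**
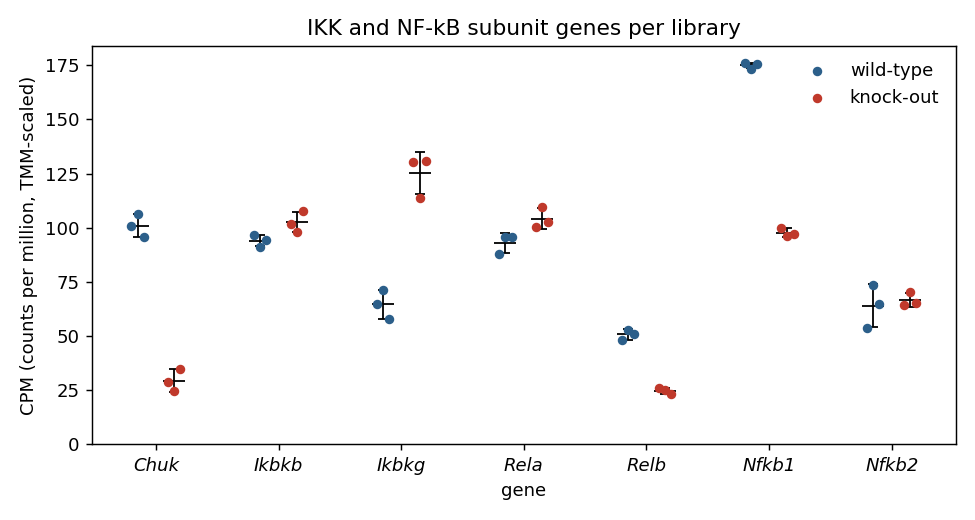
CPM of 7 IKK and NF-kB subunit genes (vertical axis, linear) in each of the 3 wild-type and 3 knock-out libraries (points), with the mean as a horizontal mark and the SD as the error bar. Chuk lay at 29.4 CPM in the knock-out against 101 in the wild type, while the points of Nfkb2 overlapped between the genotypes.

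Among the genes with the largest changes, Muc13, Reg3b and Ifitm3 were near or at 0 in the knock-out and Hoxa9 and Hoxa10 near or at 0 in the wild type. Muc13, a transmembrane mucin (ENSMUSG00000022824, chromosome 16, 33794037 to 33819934), fell from 301 ± 11 CPM to no count in any knock-out library, at least 8960-fold lower. Reg3b, an antimicrobial lectin (chromosome 6, 78370657 to 78373466), fell from 611 ± 80.4 CPM to 3 counts in all, a ratio of 18300 with a 95% counting interval of 6250 to 88600, and its neighbour Reg3g fell from 383 ± 50.4 to 0.0448 ± 0.0488 CPM. Ifitm3, an interferon-induced membrane protein, fell from 1097 ± 137 to 0.101 ± 0.00961 CPM and had the smallest p of the whole test (adjusted p = 2.8e-15). In the other direction, Hoxa9 (ENSMUSG00000038227, chromosome 6, 52223100 to 52231089), a homeobox gene of posterior body patterning, rose from no wild-type count to 149 ± 6.64 CPM, at least 3850-fold higher, and Hoxa10 rose to 186 ± 12.4 CPM from 1 count, a ratio of 14300 with a 95% counting interval of 2570 to 567000.

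Apart from Xist, which is given with the sex-linked genes below, the other genes with the largest falls were B4galnt2, a glycosyltransferase gene, at least 4100-fold lower, Nlrp6, an innate immune sensor of the intestinal epithelium, at least 3410-fold lower, Itln1, at least 2000-fold lower, Fam13a, at least 1950-fold lower, Slc14a1, at least 1770-fold lower, and Sema5a, at least 1500-fold lower, all without a count in the knock-out. Apart from the Y-linked Eif2s3y, Ddx3y and Kdm5d, also given below, the other genes with the largest rises were Flrt2, at least 1350-fold higher, Mcpt1, a mast cell protease gene, at least 1170-fold higher, Gria3, a glutamate receptor gene, at least 1050-fold higher, Bicc1, at least 900-fold higher, and Fam167a, at least 823-fold higher, all without a count in the wild type. Palmd rose from 0.0818 ± 0.0718 to 226 ± 1.54 CPM and Mucl3 from 0.0707 ± 0.0614 to 158 ± 2.77 CPM, with the smallest p among the genes that rose (adjusted p = 5.8e-15 and 5.9e-15). Bounds are against 3 counts over the pooled libraries of a genotype, which corresponds to 0.0336 CPM in the knock-out and 0.0388 CPM in the wild type, and like the intervals they cover counting error only.

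Of 13759 genes tested, 7896 (57.4%) passed an adjusted p of 0.05, with 4182 higher and 3714 lower in the knock-out. At least 2-fold differences were found for 2096 of the genes that rose and 1353 of those that fell, and at least 4-fold differences for 1241 and 782. The 3 values of one genotype did not overlap the 3 of the other for 8681 genes (63.1%), where chance gives 10%. Pearson correlations of log2 CPM across genes were 0.991 to 0.996 between libraries of one genotype and 0.872 to 0.880 between genotypes (genes are not independent replicates), and the first principal component, which separated the genotypes, held 90.1% of the variance. No 2 libraries agreed within sampling noise.

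The genotypes also differed in sex-linked transcripts, in mitochondrial transcripts and along chromosome 5. Xist, the transcript of the inactive X chromosome, had 1234 ± 331 CPM in the wild type and 6 counts in all in the knock-out, whereas the Y-linked genes Eif2s3y (80.2 ± 3.39 CPM, at least 2070-fold higher), Ddx3y (49.6 ± 13.2 CPM, at least 1280-fold higher) and Kdm5d (40.6 ± 2.25 CPM, at least 1050-fold higher) were counted only in the knock-out libraries. Uty rose to 24.6 ± 4.70 CPM from 1 wild-type count. The list of 5 sex-linked genes had 4 members that rose and 1 that fell, also adjusted over the list alone (camera adjusted p = 0.0362, and adjusted p = 0.295 with an estimated correlation), and its call was lost without any 1 of the wild-type replicates (adjusted p = 0.0605 without wild-type replicate 1, 0.0569 without replicate 2 and 0.0973 without replicate 3). Every library of a genotype therefore had the sex-linked expression of 1 sex, and genotype and sex could not be separated in any comparison here. Ikbkg and Gria3, given above, lie on chromosome X. Mitochondrially encoded transcripts took 2.61 ± 0.738% of the counts in the knock-out and 7.06 ± 0.769% in the wild type. The median log2 fold change of the 685 chromosome 5 genes with a mean of at least 5 CPM lay 0.43 above that of the other autosomes, and the other autosomes lay between -0.10 and 0.03. On chromosome 5, 58.7% of these genes were called higher and 10.1% lower. Without genes of chromosomes X, Y and 5 and the mitochondrial genome, an alternative chosen after seeing the data, 7019 of 12347 genes passed, 51.5% of them higher.

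**Figure D2:**
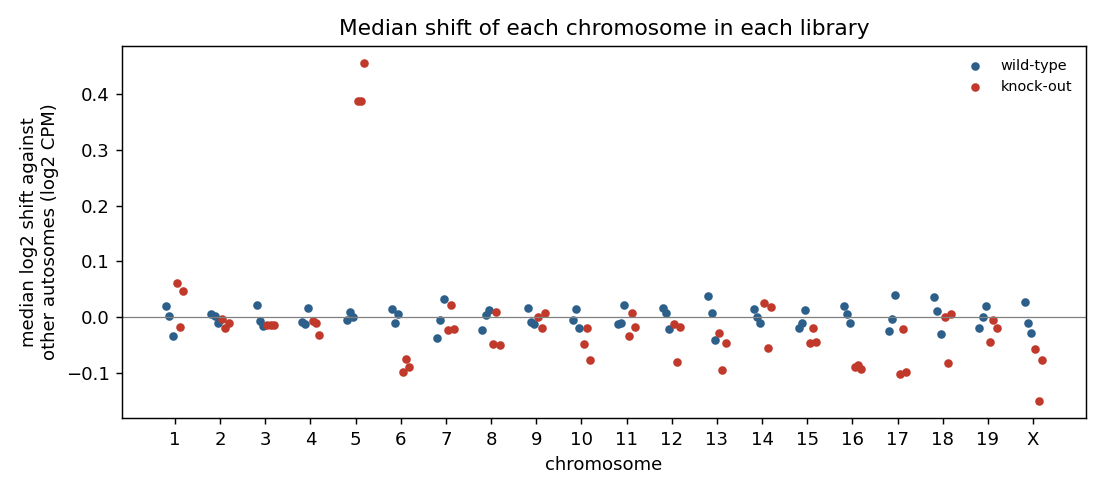
Median log2 CPM shift of each chromosome's genes against the genes of the other autosomes (vertical axis) for each library (points), relative to the mean of the wild-type libraries, leaving out the library itself where it is wild type. The 3 knock-out libraries lay at 0.39, 0.39 and 0.46 on chromosome 5 and between -0.10 and 0.06 on the other autosomes.

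Genes of crypt stem cells and Wnt targets fell as groups. Their lists share Lgr5, Ascl2, Axin2, Rnf43, Znrf3, Tnfrsf19, Cd44, Ephb2 and Ephb3, so these results are not independent. Of 24 tested crypt stem cell genes, 17 fell and 4 rose, with a median log2 fold change of -1.50 (camera adjusted p = 4.48e-05, and adjusted p = 0.217 with an estimated correlation). Smoc2, a matricellular protein of stem cells, fell from 383 ± 33.1 to 0.205 ± 0.15 CPM, Clca3b fell 72.6-fold, and Lgr5, the receptor that marks cycling crypt stem cells (named after its values were seen), fell 41.3-fold to 1.52 ± 0.787 CPM. The 4 that rose were Prom1, Cd44, Zbtb38 and Tgif1. Of 24 tested Wnt targets, 16 fell and 4 rose, with a median of -2.04 (adjusted p = 4.77e-04, and adjusted p = 0.217 with an estimated correlation). Axin2, a feedback inhibitor of Wnt signalling on both lists, fell 5.57-fold to 69.4 ± 4.13 CPM, and Kcne3, a potassium channel subunit, fell 10.3-fold. The Wnt targets that rose were Notum, Ccnd1, Cd44 and Wnt10a. Among 9 reserve stem cell genes 4 rose and 4 fell (adjusted p = 0.671). Hopx fell 28.8-fold and Lrig1 5.72-fold, and Clu, which is also on the regenerative list, rose 7.88-fold to 1695 ± 70.3 CPM. Counts were the same adjusted over the list alone for these 3 lists.

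Most tested goblet, Paneth, enterocyte and enteroendocrine genes fell. The Paneth list shares Spink4 with the goblet list, Mmp7 with the Wnt list and Sox9 with the crypt stem cell list. Of 19 tested goblet cell genes, 17 fell and 1 rose, with a median log2 fold change of -4.73 (adjusted p = 4.95e-07, and adjusted p = 0.251 with an estimated correlation), and besides Muc13 these included Fcgbp, a mucus protein, 226-fold lower at 2.72 ± 0.117 CPM, and Agr2, 46.4-fold lower. The goblet median was -5.34 without knock-out replicate 1. Of 17 tested Paneth cell genes, 15 fell and 1 rose (adjusted p = 1.39e-06, and adjusted p = 0.217 with an estimated correlation). The Paneth median of fitted values was -8.35, and -6.41 with the 9 genes that had no count in 1 genotype set at their bound, and the fitted median was -9.54 with a filter of 1 CPM in 3 libraries. Lyz1, the Paneth cell lysozyme, fell from 163 ± 21.7 CPM to 1 count, a ratio of 14300 with a 95% counting interval of 2570 to 566000. Of 18 tested enterocyte genes, 12 fell and 4 rose, with a median of -1.63 (adjusted p = 4.29e-03, and adjusted p = 0.217 with an estimated correlation). Slc5a1, the sodium-glucose transporter, fell from 72.8 ± 8 to 0.0693 ± 0.0404 CPM, Cdhr5 fell 510-fold and Myo1a, a brush border myosin, 18.8-fold, whereas Apob, Mttp, Rbp2 and Krt20 rose. The enterocyte median was -3.04 without wild-type replicate 1, and Cdhr5 was 1660-fold lower without knock-out replicate 2, 337-fold lower without replicate 3 and 802-fold lower with limma voom. Of 8 tested enteroendocrine genes, 6 fell and 1 rose, with a median of -4.88 at the bounds (adjusted p = 0.0465, and adjusted p = 0.5 with an estimated correlation). Reg4 fell 47.8-fold and Insm1 fell to 3 counts, a ratio of 51.9 with an interval of 17.4 to 255, while Cpe, a prohormone-processing enzyme gene, rose 70.5-fold. Without knock-out replicate 3 the fitted enteroendocrine median moved from -5.55 to -6.15 and the fitted fall of Insm1 from 45.9-fold to 80.3-fold. Reg4 was 87.7-fold lower without that library and 80-fold lower with limma voom. That call was lost with a filter of 1 CPM in 3 libraries (adjusted p = 0.164) and without chromosomes X, Y, 5 and mitochondrial genes (adjusted p = 0.0603). Counts adjusted over the list alone were the same for these 4 lists.

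Genes of fetal and regenerating epithelium rose. Of 23 tested members, 20 rose and 2 fell, with a median log2 fold change of 2.04 (adjusted p = 7.76e-09, and adjusted p = 0.217 with an estimated correlation), and the counts were the same adjusted over the list alone. Anxa3 rose 4.24-fold to 1249 ± 58.3 CPM, Gja1, a gap junction protein, 13.1-fold, and Ctse, an aspartic protease, 102-fold to 306 ± 37.0 CPM. Ly6a, the gene of the Sca-1 antigen of regenerating crypts (named after its values were seen), rose 2.27-fold. Of 26 tested targets of the coactivator Yap, 19 rose and 5 fell (20 and 5 adjusted over the list alone), with a median of 1.53 (adjusted p = 5.99e-05, and adjusted p = 0.217 with an estimated correlation). Ankrd1 rose 50.4-fold to 199 ± 13.7 CPM, Igfbp3 159-fold and Fjx1 from 4 counts in all to 88.1 ± 6.88 CPM. The Yap and fetal lists share Msln and Il33, so these results are not independent.

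Keratinocyte and stomach genes rose as well. Of 17 tested squamous epithelium genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 fold change of 6.13 fitted and 5.51 at the bounds (adjusted p = 1.64e-06, and adjusted p = 0.217 with an estimated correlation). Sprr1a, a precursor of the cornified envelope, rose 106-fold to 958 ± 40.5 CPM, Krt6a 143-fold to 70.8 ± 7.56 CPM and Lor 12.8-fold to 886 ± 122 CPM. Of 10 tested gastric epithelium genes, 6 rose and 2 fell, also adjusted over the list alone, with a median of 1.74 (adjusted p = 0.0362, and adjusted p = 0.295 with an estimated correlation). Tff1, a trefoil peptide of the gastric surface, rose from 0.168 ± 0.235 to 93.3 ± 19 CPM and Tff2 28.8-fold. Ctse and Vsig1 are on the gastric and the fetal list, and Ly6d is on the squamous and the fetal list. The gastric median was 2.87 without wild-type replicate 2 and 4.85 with a filter of 1 CPM in 3 libraries. The gastric call was lost without wild-type replicate 1 (adjusted p = 0.0642) and without chromosomes X, Y, 5 and mitochondrial genes (adjusted p = 0.0732).

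**Figure D3:**
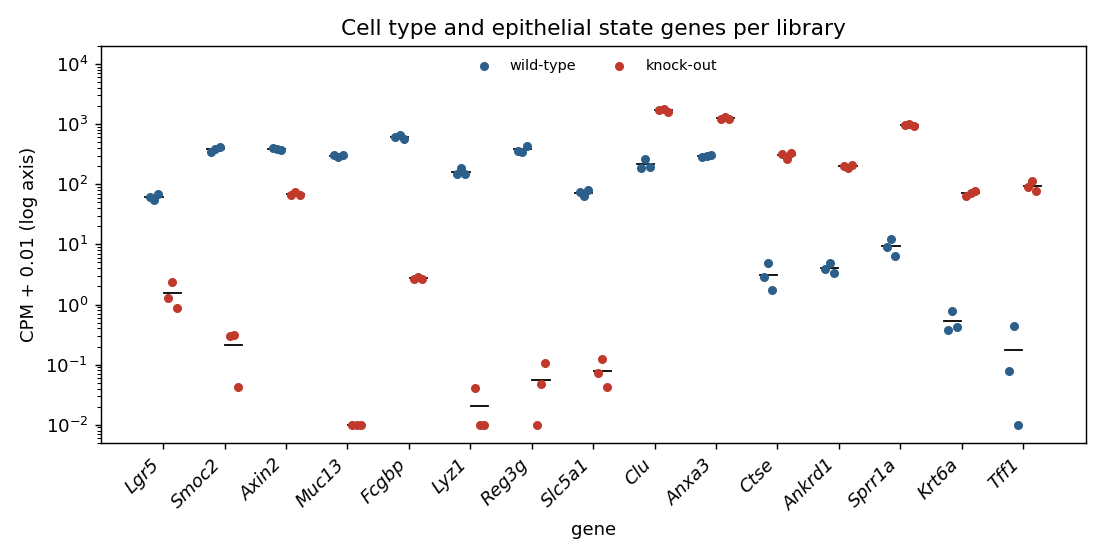
CPM plus 0.01 (vertical axis, log scale) of 15 cell type and epithelial state genes in each of the 3 wild-type and 3 knock-out libraries (points), with the mean as a line. The 8 genes from Lgr5 to Slc5a1 lay lower in all 3 knock-out libraries and the 7 from Clu to Tff1 higher, with Sprr1a at 958 CPM against 9.23.

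Targets of canonical NF-kB signalling went both ways. Of 28 tested targets, 12 rose and 11 fell (13 and 11 adjusted over the list alone). The list did not pass (camera adjusted p = 0.749), although fry called it upward (adjusted p = 0.0189). Targets of non-canonical NF-kB signalling had no list of their own. Tnfaip2 rose 37.5-fold, the neutrophil chemokine gene Cxcl5 150-fold to 153 ± 25.1 CPM and Tnfaip3, a negative regulator of NF-kB, 9.05-fold to 200 ± 27.5 CPM, while Nfkbia, Tnf, Birc3 and Sod2 were among those that fell. Without wild-type replicate 2, Cxcl5 was 253-fold higher. Under upper-quartile scaling 11 rose and 11 fell. Of 26 pathway components, 7 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.938), among them Tnfrsf12a, the TWEAK receptor, 4.09-fold higher, and Tnfrsf11a, the RANK receptor, 8.22-fold lower. The 8 that fell include Chuk, the targeted gene itself.

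Proliferation and respiratory chain genes fell by small amounts, and targets of p53 and antioxidant genes rose. Of 35 proliferation genes, 29 fell and 0 rose (31 and 0 adjusted over the list alone), with a median log2 fold change of -0.54 (adjusted p = 3.39e-08, and adjusted p = 0.257 with an estimated correlation), and Bub1b, Kif11 and Top2a fell 2.02-fold, 1.89-fold and 1.76-fold. Of 24 p53 targets, 20 rose and 2 fell (20 and 3 adjusted over the list alone), with a median of 0.77 (adjusted p = 8.19e-06, and adjusted p = 0.257 with an estimated correlation). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 3.33-fold to 428 ± 13.6 CPM, Perp 3.92-fold and Phlda3 3.01-fold. Of 26 antioxidant genes, 22 rose and 2 fell (23 and 2 adjusted over the list alone), with a median of 0.79 (adjusted p = 1.13e-06, and adjusted p = 0.295 with an estimated correlation), led by Aldh3a1, 125-fold to 422 ± 78.5 CPM, Me1, 5.09-fold, and Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, 4.48-fold. Gpx2 and Gstm3 fell. Of 31 nuclear genes of oxidative phosphorylation, 28 fell and 0 rose (30 and 0 adjusted over the list alone), with a median of -0.66 (adjusted p = 1.61e-09, and adjusted p = 0.300 with an estimated correlation), Sdhd 2.17-fold and Uqcrb 2.21-fold. All 7 tested mitochondrially encoded genes fell, also adjusted over the list alone, with a median of -1.37 (adjusted p = 3.46e-04, and adjusted p = 0.295 with an estimated correlation), mt-Co1 2.65-fold from 19629 ± 2440 CPM. The other 6 of the 13 mitochondrial protein genes, such as mt-Co3, had no count in any library. The mitochondrially encoded list was fixed as a sign of RNA quality, and whether RNA quality differed between the genotypes was not tested. Of 27 glycolysis and hypoxia genes, 18 fell and 5 rose, also adjusted over the list alone, with a median of -0.65 (adjusted p = 0.0172, and adjusted p = 0.658 with an estimated correlation). Pfkp fell 7.75-fold and Vegfa 18.9-fold, and Hk1 rose 2.83-fold.

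Junction, mesenchymal and stress genes moved as well. Of 25 epithelial junction genes, 16 fell and 6 rose, also adjusted over the list alone, with a median log2 fold change of -0.27 (adjusted p = 0.0172, and adjusted p = 0.251 with an estimated correlation). Epcam fell 2.22-fold, Dsc2 3.95-fold and Cldn15 94.5-fold (182-fold with limma voom), and the call was lost without chromosomes X, Y, 5 and mitochondrial genes (adjusted p = 0.0821). Of 9 tested mesenchymal transition genes, 8 rose and 1 fell, also adjusted over the list alone, with a median of 2.93 (adjusted p = 2.87e-03, and adjusted p = 0.217 with an estimated correlation), among them Mmp14, 7.63-fold to 470 ± 4.48 CPM, and Tgfb1, 17.2-fold. The mesenchymal transition median was 4.09 without wild-type replicate 1 and 3.56 without replicate 3. The remaining 15 members of that list, including Vim, Zeb1, Snai1 and Twist1, had too few counts to be tested. Of 22 immediate early and heat shock genes, which respond to handling, 9 rose and 3 fell, also adjusted over the list alone, with a median of 0.41 (adjusted p = 0.0465, and adjusted p = 0.295 with an estimated correlation), with Dusp1 6.86-fold, Ier3 3.59-fold and Klf4 3.09-fold higher. That call was lost without knock-out replicate 3 (median 0.203, adjusted p = 0.0575) and with the filter of 1 CPM (adjusted p = 0.0579), and the median was 0.672 without wild-type replicate 2 and 0.232 without replicate 3.

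Markers of other cell types were mostly too low to be tested. Of 24 immune cell genes, 6 were tested, of which 5 rose and 0 fell (5 and 1 adjusted over the list alone), with a median log2 fold change of 2.82 (adjusted p = 0.0362, and adjusted p = 0.263 with an estimated correlation). They included S100a9, which is also on the squamous list, at 9.19 ± 1.56 CPM, Csf1r, 15.9-fold to 10.9 ± 0.361 CPM, and Cd14, 2.79-fold to 107 ± 10.4 CPM, and Csf1r was 46.2-fold higher without wild-type replicate 1 and 38.1-fold higher with limma voom. The immune call was lost, with a smaller median, without knock-out replicate 1 (median 1.81, adjusted p = 0.0805), 2 (median 1.75, adjusted p = 0.110) or 3 (median 1.76, adjusted p = 0.0630) and without wild-type replicate 1 (median 1.42, adjusted p = 0.124). Of 15 fibroblast genes, 3 were tested and rose, Col6a1 at least 409-fold to 15.8 ± 1.47 CPM, Col6a2 at least 35.0-fold and Col1a1 from 2 counts to 0.666 ± 0.185 CPM, too few members for a list test. Of 5 tested smooth muscle and endothelial genes, 3 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.137), with Acta2 down from 12.5 ± 4.73 to 0.117 ± 0.111 CPM, Tek 42.4-fold lower and Vwf 14.9-fold lower. Of 3 tested neural and glial genes, Ret rose 16.6-fold to 9.11 ± 0.460 CPM.

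Among genes of gut position, 6 of 8 tested distal small intestine and colon genes fell and 1 rose (6 and 2 adjusted over the list alone), with a median log2 fold change of -3.31 at the bounds (adjusted p = 0.0220, and adjusted p = 0.217 with an estimated correlation). They included Reg3b, Slc10a2, the ileal bile acid transporter, 4.50-fold lower, and Ang4, at least 253-fold lower, and the call was lost without knock-out replicate 2 (adjusted p = 0.110). The fitted distal median of -3.51 was -2.05 without that library and -2.05, -2.08 and -1.82 without wild-type replicates 1, 2 and 3, and -2.17 with a filter of 1 CPM in 3 libraries. Of 14 proximal small intestine genes, 8 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.15), with Pdx1, a homeobox gene of the duodenum, down from 40.9 ± 2.78 CPM to 1 count, a ratio of 3680 with an interval of 660 to 145000, and Onecut3 up to 17.5 ± 0.718 CPM. Of 22 tested genes neighbouring Chuk, 13 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -0.49 (adjusted p = 0.0139, and adjusted p = 0.217 with an estimated correlation), Cpn1 4.05-fold and Scd1, a fatty acid desaturase, 1.60-fold lower, while Pax2 rose at least 103-fold to 4 ± 0.646 CPM.

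**Figure D4:**
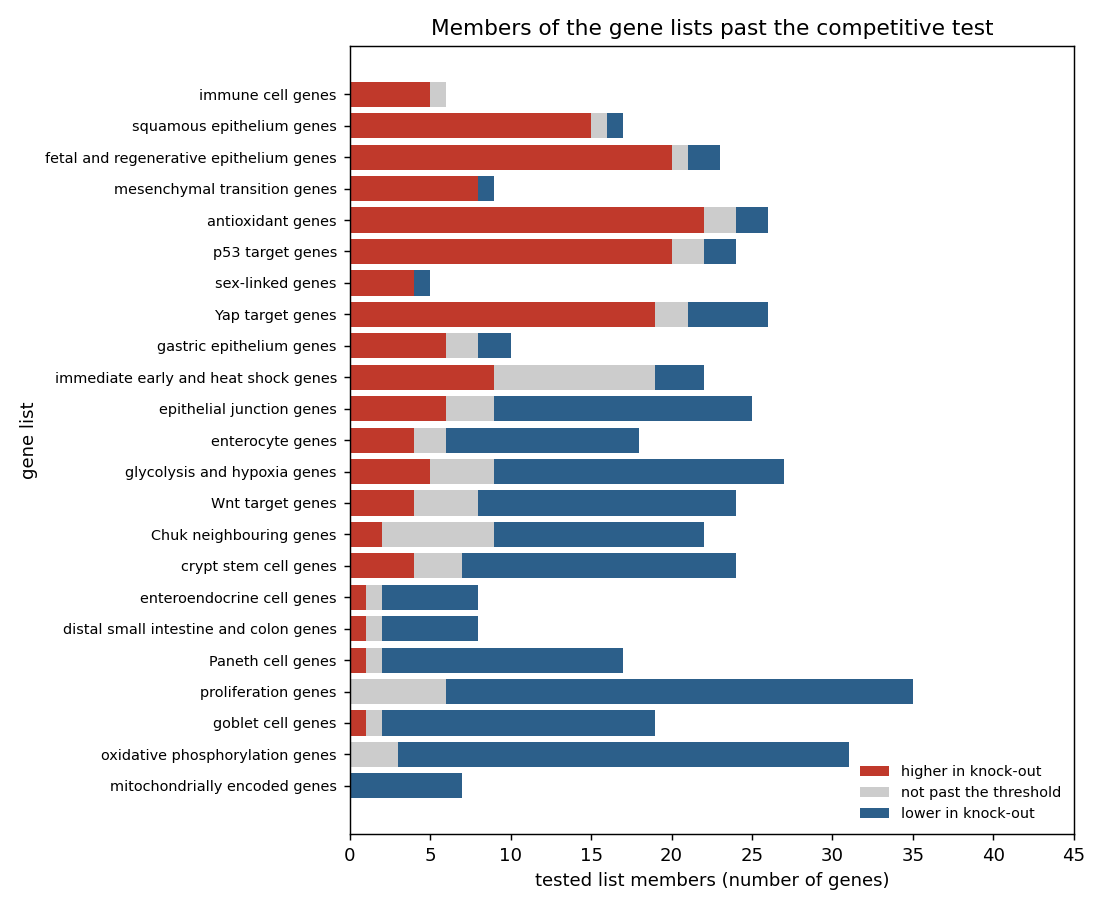
Number of tested members (horizontal axis) of the 23 gene lists past the camera test that were called higher in the knock-out, called lower, or not past the threshold. All called members of the proliferation (29), oxidative phosphorylation (28) and mitochondrially encoded (7) lists were lower, and 20 of 23 fetal and regenerative genes were higher.

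The remaining lists did not pass with camera, and their called members went both ways. Of 20 retinoid genes, 11 rose and 5 fell (adjusted p = 0.101), with the retinol receptor gene Stra6 166-fold and Adh7 137-fold higher and Isx, an intestinal homeobox gene, 274-fold lower. Without wild-type replicate 3, Adh7 was 220-fold higher. Of 14 Notch genes, 4 rose and 7 fell (adjusted p = 0.465), with the receptor Notch3 5.72-fold and its ligand Jag1 5.73-fold higher and the ligand Dll4 20.6-fold lower. Of 33 interferon response genes, 9 rose and 10 fell (adjusted p = 0.966), with Isg20 10.1-fold higher, Ifit1bl1 89.5-fold lower and the RNA sensor Ddx58 5.46-fold lower. Of 13 antigen presentation genes, 5 rose and 6 fell (adjusted p = 0.671), with H2-T23 3.79-fold higher and Psmb10 4.65-fold and H2-Q4 2.88-fold lower. Of 12 tuft cell genes, 6 rose and 4 fell (adjusted p = 0.671), with Ptgs1 19.9-fold and Avil 20.0-fold higher and Trpm5 17.9-fold lower. Of 12 M cell genes, 5 rose and 4 fell (adjusted p = 0.764), with Msln 4.11-fold higher and Tnfrsf11b 7.82-fold lower, and under upper-quartile scaling 4 rose and 5 fell. Of 26 unfolded protein response genes, 7 rose and 7 fell (adjusted p = 0.938), with Asns 2.71-fold and Herpud1 2.12-fold lower and Pdia4 1.43-fold higher. Of 25 cholesterol synthesis genes, 9 rose and 9 fell (adjusted p = 0.662), with Stard4 3.18-fold and Acat2 2.19-fold lower. Under upper-quartile scaling, 6 unfolded protein response genes rose and 7 fell, and 6 cholesterol genes rose and 9 fell. Counts adjusted over the list alone were the same for these 8 lists. The median, the mean and the test differed in sign for the tuft cell list (median -0.20, test upward), the M cell list (median 0.36, mean -0.24), the interferon list (median 0.18, test downward), the unfolded protein response list (median 0.13, mean -0.07), the cholesterol list (median 0.00, mean -0.15) and the NF-kB components (median 0.01, mean -0.09). Over the alternatives, these medians ran from -0.35 to 1.20 for the tuft cell list, whose median was above 0 with the filter of 1 CPM alone, from 0.00 (without wild-type replicate 1) to 0.51 for the M cell list, from 0.06 to 0.25 for the interferon list, from 0.03 to 0.15 for the unfolded protein response list, from -0.10 to 0.05 for the cholesterol list and from -0.05 to 0.06 for the NF-kB components.

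Of the 36 lists tested, 23 passed with the preset correlation, 10 upward and 13 downward, and 0 passed with a correlation estimated from the 6 libraries (camera), where the lowest adjusted p was 0.217 and 4 lists had an unadjusted p under 0.05. Calls were lost even below the preset 0.01, at estimated correlations of -0.0145 (crypt stem cell), -0.0255 (mesenchymal transition) and -0.1085 (distal gut). Correlated genes alone therefore do not account for the loss. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries, so a list passes less easily. The self-contained test fry called 30, among them 7 lists that camera with the preset correlation did not call. The NF-kB target, retinoid, tuft cell and M cell lists were called upward. The reserve stem cell, proximal small intestine, and smooth muscle and endothelial lists were called downward. Reads that could be shared between near-identical copies (Reg3b and Reg3g, Lyz1 and Lyz2, the Defa defensins, the Gsta genes, Ddx3y and its X-linked copy) or between overlapping genes (Hoxa3 spans Hoxa4, Hoxa5 and Hoxa6) leave the split within each such group uncertain, since how they were counted is not given in the sources used here.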

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

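All 18 alternatives left the count of changed genes within 1.5 times the 7896 reported, from 6397 at an adjusted p of 0.01 to 8899 without knock-out replicate 2, and leaving out 1 library gave 7077 to 8899. Upper-quartile scaling moved the median log2 fold change of all genes to -0.05 and the share of calls that were higher from 53% to 48.3%. Of the named genes' alternative values, 2157 kept their direction and side of the threshold, and 1 reversed, Nfkb2, with a log2 fold change of -0.049 without wild-type replicate 1 and 0.172 without wild-type replicate 2, the extremes over the libraries left out, which was past the threshold in neither fit; the cause was not tested. Chuk stayed between -1.92 and -1.69. With an estimated correlation 0 gene lists passed, 0 higher and 0 lower; over the lists' alternatives 382 kept their call, 39 lost it and 7 gained one, all 7 with fry. Leaving out chromosomes X, Y and 5 and mitochondrial genes, chosen after seeing the data, left 18 lists, and the sex-linked and mitochondrially encoded lists could then not be tested. The replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated at 0.06, -0.06 and -0.11. With the replicate number as a block, 7432 genes (3959 higher, 3473 lower) and 22 lists passed, Chuk had -1.78, and the immediate early list (adjusted p = 0.065) no longer passed. Depth limits the fold changes of genes under about 0.04 CPM in a genotype, where it has fewer than 3 counts in all. Genes too low for the filterByExpr filter (minimum count 10, minimum total 15) were not tested.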

Other observations

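The tests of a chromosome copy difference and of passenger DNA as the source of most changes, and all tests of the Hoxa pattern, were chosen only after the result was seen, as were the genes and gene clusters named in this part.

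The Hoxa cluster was on in the knock-out along most of its length. All 9 tested Hoxa genes were higher, with 43510 counts in the knock-out libraries against 17 in the wild type, and levels were highest for Hoxa7 (115 ± 10.2 CPM), Hoxa9 (149 ± 6.64) and Hoxa10 (186 ± 12.4) and lower for Hoxa3 (9.71 ± 1.32) and Hoxa5 (19.9 ± 4). Hoxa11 and Hoxa13, the next genes of the cluster, had no count in any library. None of the Hoxc and Hoxd genes had a count in any library, and of the Hoxb genes Hoxb4 alone was tested and rose, to 1.76 ± 0.662 CPM. Among single transcription factor genes, Cdx2, a master regulator of intestinal identity, fell 9.38-fold to 20.6 ± 1.30 CPM, Cdx1 fell from 6.38 ± 0.2 CPM to no count, Hnf4a fell 2.73-fold and Gata4 3.24-fold. Gata6 rose from 0.131 ± 0.0946 to 25.3 ± 3.15 CPM, Onecut2 rose 7.29-fold to 591 ± 139 CPM, and Foxj1, a regulator of motile cilia, rose from 0.648 ± 0.248 to 152 ± 15.1 CPM. Sox17, an endoderm factor, fell from 84.9 ± 12.3 to 0.180 ± 0.204 CPM.

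Ctnnb1, the gene of beta-catenin, rose 2.41-fold to 3740 ± 303 CPM from 1550 ± 59.3, while most Wnt targets fell. Further genes that rose from low levels include Gabrp, a GABA receptor subunit gene, at 1252 ± 53.7 CPM from 0.946 ± 0.552, Cav1, the gene of caveolin 1, at 893 ± 105 CPM from 4.72 ± 2.73, and Ptgs2, the gene of an inducible prostaglandin synthase, at 257 ± 66.1 CPM from 2.66 ± 1.82. The keratin genes Krt7 and Krt19 rose 3.19-fold and 2.69-fold, to 3249 ± 402 and 3970 ± 557 CPM.

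The 7896 genes that changed between the genotypes cannot be assigned to the loss of Chuk alone. The design of 3 against 3 libraries gives 10 splits, too few for a share under 0.05, and 1 of them, the real one, reached 7896 genes while the highest of the others had 0 by edgeR (30 to 506 at an unadjusted p under 0.05). The other splits mixed the genotypes within each group, so the genotype difference added to their spread. Their counts therefore do not measure chance. X- and Y-linked genes were 3.27% of the called genes, a share kept low because only 415 X and 6 Y genes were tested. Of the 13150 tested autosomal genes over 10 Mb from Chuk, 57.2% were called. This argues against X- and Y-linked genes, or genes altered by neighbouring DNA that travelled with the floxed allele, making up most changes. The share called within 10 Mb of Chuk was 1.14 times that on the other autosomes (95% interval 1.01 to 1.28), so an effect of such DNA on some of those 155 genes stays open, as does an effect through them on genes elsewhere, which was not tested. The number of libraries whose Xist count went against the rest of their genotype was 0, so the sex of the source animals acting on autosomal genes cannot be told apart from genotype, nor can differences between the individual tumours or lines, which were not tested.

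The upward shift of chromosome 5 was present in all 3 knock-out libraries, 0.41 ± 0.04 on the log2 scale against 0.00 ± 0.01 in the wild type (mean ± SD, n = 3 each). The lowest knock-out library had 0.388, which argues against 1 aberrant library, and the shift against genes matched on GC content, exon length and mean CPM was 0.411, which argues against these properties. Along the chromosome, the lowest median of 10 blocks of neighbouring genes was 0.249 and the highest 0.754, and 136 blocks on the other autosomes lay between -0.292 and 0.238. A candidate explanation is an extra copy in the knock-out cells, where 3 copies against 2 in every cell would give 0.58, or a lost copy in the wild-type cells, where 2 against 1 would give 1 on the log2 scale, but the shift of the whole chromosome lay below both and was uneven, with 2 blocks (0.754 and 0.607) above 0.58. This is a hypothesis from expression alone, no DNA was analysed here, and a shift shared by 3 libraries may mean that they came from 1 line.

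The rise of Hoxa5 to Hoxa10 with the loss of Pdx1 was present in all 3 knock-out libraries, where the lowest Hoxa9 CPM was 91.5% of the highest. Vim and Col3a1, abundant transcripts of mesenchyme, together reached 0.0942% of the Hoxa9 CPM, which argues against mesenchymal cells in the knock-out cultures as the source, although Col6a1 (to 15.8 ± 1.47 CPM), Col6a2 and Col1a1 rose, as did 8 of 9 tested mesenchymal transition genes, and the other 12 fibroblast genes had too few counts to be tested. Of the distal gut genes, 1 rose and 6 fell, a difference of -5, but these are genes of mature cells and enterocyte genes fell too, so a more distal origin of the knock-out cells cannot be told apart from a loss of mature enterocyte expression. The loss of IKKa, a different tumour of origin and a different sex stay open as biological explanations and were not tested.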
